A study of Mus musculus with 6 samples.

How the data were processed

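The study measured messenger RNA in intraepithelial lymphocytes (IEL), the T cells that lie within the lining of the mouse small intestine, on Affymetrix arrays. The authors deposited signal intensity from MAS5 (version not given), 1 value per probe set and array, in linear units after scaling each array to a common trimmed mean. The trimmed mean with 2% of the values left out at each end was about 500.4 on all 6 arrays, so the further factor applied here to each array lay between 0.999915 and 1.00006. Detection calls were not used, and the positions of the probes were not available.

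The table held 12488 probe sets, of which 66 were controls. Of the others, 10833 carried 1 gene symbol, 396 carried several and 1193 had no entry in the annotation. Values under the 20th percentile of all values (signal 15.3, log2 3.94) were set to it, and log2 was taken. Probe sets were tested if at least 2 arrays lay above the 40th percentile (signal 56.4), which left 8299, of which 7399 carried 1 symbol and stood for 6109 genes. No 2 arrays shared more than 45 equal values, so none was a copy of another.

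Each of the 3 comparisons between subsets was fitted with limma 3.58.1 in R 4.3.3 on all 6 arrays, with the intensity trend in eBayes, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. The 2 replicates per subset came from 2 experiments, each with a new pool of 20 mice from which all 3 subsets were sorted, so the replicate number pairs the arrays. The design fixed before the data were examined had no term for the experiment. A fit with the experiment as a block was planned then as an alternative. Deviations of the arrays from the mean of their subset correlated between subsets with Pearson's r, across probe sets, of 0.618, 0.713 and 0.603. Both fits are reported for the counts of called probe sets. Tests of gene lists are those without the block unless stated otherwise. Standard errors are those of the fit with the block unless stated otherwise. They are limma's moderated values, pooled over the 3 subsets and drawn toward the intensity trend. A probe set therefore has the same standard error in each comparison, and it is not the spread of the 2 arrays of a subset. P-values of limma measure the spread between samples, each of which was a pool of 20 mice, and not that between mice. With the block, it is the spread left after the difference between experiments is taken out.

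Gene lists were fixed before the data were examined and tested with camera on 1 probe set per gene, the brightest, with a preset correlation of 0.01. The 18 lists and 3 comparisons gave 54 tests, adjusted together. At the preset correlation, camera sets the genes of a list against the other genes. Its p-values then rest on the spread between genes and do not measure that between samples. Camera with an estimated correlation and fry were run beside it. Sort markers and antigen receptor genes formed a label check and were left out of the genes with the largest change, but the counts of called probe sets include them, and Cd247, Cd3d, Cd3e and Cd3g are also in the list of proximal T cell receptor signalling. A further 10 lists held markers of other cell types and of the sex of the pooled mice, and are given as medians.

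The named genes followed a rule fixed before the data were examined. Per comparison and fit, it took the 10 genes with the largest change in each direction among probe sets past the threshold that carried 1 symbol and whose 2 arrays of 1 subset both lay above both arrays of the other. Where fewer than 5 passed in a direction, it took the 5 with the smallest p. It added up to 4 members of each list with the smallest p without a block, and the sort markers. The rule gave 269 pairs of gene and comparison. The text prints the genes with the largest change, the first members by p of lists that passed, and of the other lists the members called with the block. The dependence on processing was computed for all 269, printed or not.

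Other settings fixed before the data were examined were quantile normalization, no further scaling, a floor at the 10th or 30th percentile or an added constant in its place, no filter or a filter at the 60th percentile, eBayes without the trend, only the arrays of the 2 groups, the replicate block, each array left out in turn, an adjusted p under 0.10, and for lists an estimated correlation, fry and the mean of a gene's probe sets. The replicate block together with each of these was added after seeing the data.

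In simulated arrays of 8299 probe sets, the fit without a block called 0 of 50 probe sets changed by each of 1, 2, 3 and 4 log2 units. The fit with the block called 18%, 92%, 100% and 100% of them, and also 17 probe sets that were unchanged. Each probe set had the same difference between experiments in all 3 subsets, as the block assumes, with the noise of the blocked fit. Only probe sets bright enough to fall without reaching the floor were changed. These rates therefore favour the fit with the block and need not hold for the measured arrays. A list of 20 simulated genes shifted by 1 log2 unit had an adjusted p of 7.09e-14, and 0 unshifted lists were called by camera. The noise was drawn independently for each gene, so this cannot show how often camera calls unshifted lists of correlated genes. The correlations that camera estimated for the measured lists, without a block, ranged from −0.046 to 0.29.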

Results

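The series compared 3 subsets of mouse small intestinal IEL that differ in antigen receptor and CD8 form. They are named here TCRab CD8aa, TCRab CD8ab and TCRgd CD8aa, after the type of T cell receptor and the CD8 dimer. Conventional CD8 T cells carry the CD8ab form, and the CD8aa form is typical of the unconventional IEL of the gut. Each subset was measured on 2 arrays, 1 in each of 2 experiments. The titles of some samples write TCRgb where their source descriptions write TCRgd, and the source descriptions were followed. The median signal of the arrays ranged from 83.4 to 113, and 17.1% to 24.5% of the probe sets lay at the floor. With 2 arrays per subset, the number of arrays limits the precision of each value below.

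The transcripts of the sort markers separated TCRab CD8ab from the CD8aa subsets. Cd8b1, which encodes the beta chain of CD8, was far lower in both CD8aa subsets, by log2 −8.23 ± 0.75 in TCRab CD8aa and −7.24 ± 0.75 in TCRgd CD8aa against TCRab CD8ab (SE, n = 2). Cd8a, the chain all 3 subsets share, had log2 differences of 0.18 ± 0.28 and 0.11 ± 0.28 from TCRab CD8ab (SE, n = 2). Trgv4, a variable segment of the gamma receptor chain, was higher in TCRgd CD8aa by 3.53 ± 0.29 and also in TCRab CD8aa by 1.66 ± 0.29. Probe sets for Trbv13-2 and Trav9d-3, segments of the beta and alpha chains, were lower in TCRgd CD8aa by −2.76 ± 0.47 and −2.42 ± 0.40. These calls were those of limma with the experiment as a block, with adjusted p of 0.0016 and 0.00332 for Cd8b1, 0.000908 and 0.0353 for Trgv4, and 0.04 and 0.0382 for Trbv13-2 and Trav9d-3. Other tested probe sets of Trbv13-2 (−1.39) and Trav9d-3 (−0.85 and −1.79) in TCRgd CD8aa against TCRab CD8ab did not pass in that fit. Those of Trbv1 (−0.736 and −3.541) and Trgv1 (0.867) did not pass there either. The brighter Trbv1 probe set had log2 signals of 14.59 and 13.3 in TCRgd CD8aa in experiments 1 and 2. Trgv1 had 12.97 and 12.78 in TCRab CD8ab, so signal for these segments did not mark the receptor type. Between the 2 CD8aa subsets no marker or receptor segment passed in either fit, with 1.87 ± 0.29 for Trgv4 (adjusted p = 0.145) and −2.76 ± 0.40 for Trav9d-3 (adjusted p = 0.111) in TCRgd CD8aa against TCRab CD8aa. Without the block none passed in any comparison, the smallest adjusted p of these genes being 0.533. In experiment 2 the log2 signal of Cd8b1 was 9.58 in TCRgd CD8aa, against 4.81 in experiment 1. Its differences from TCRab CD8ab were −9.295 in experiment 1 and −5.176 in experiment 2, a wider spread than the pooled standard error conveys.

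The 2 experiments differed more than the subsets. Of 8299 probe sets, 2827 differed between experiments, 1138 higher and 1689 lower in experiment 2. Arrays of 1 experiment correlated with each other at 0.874 to 0.964 across probe sets, and arrays of 1 subset in different experiments at 0.771 to 0.837. The ratio of the 3′ to the 5′ control probe set of beta-actin was 1.41 to 1.76 in experiment 1 and 40.4 to 52.2 in experiment 2. Across probe sets, which are not independent replicates, the log2 differences of the 2 experiments correlated with Pearson's r of 0.252 for TCRab CD8aa against TCRab CD8ab, 0.12 for TCRgd CD8aa against TCRab CD8ab and 0.0024 for TCRgd CD8aa against TCRab CD8aa.

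**Figure D1:**
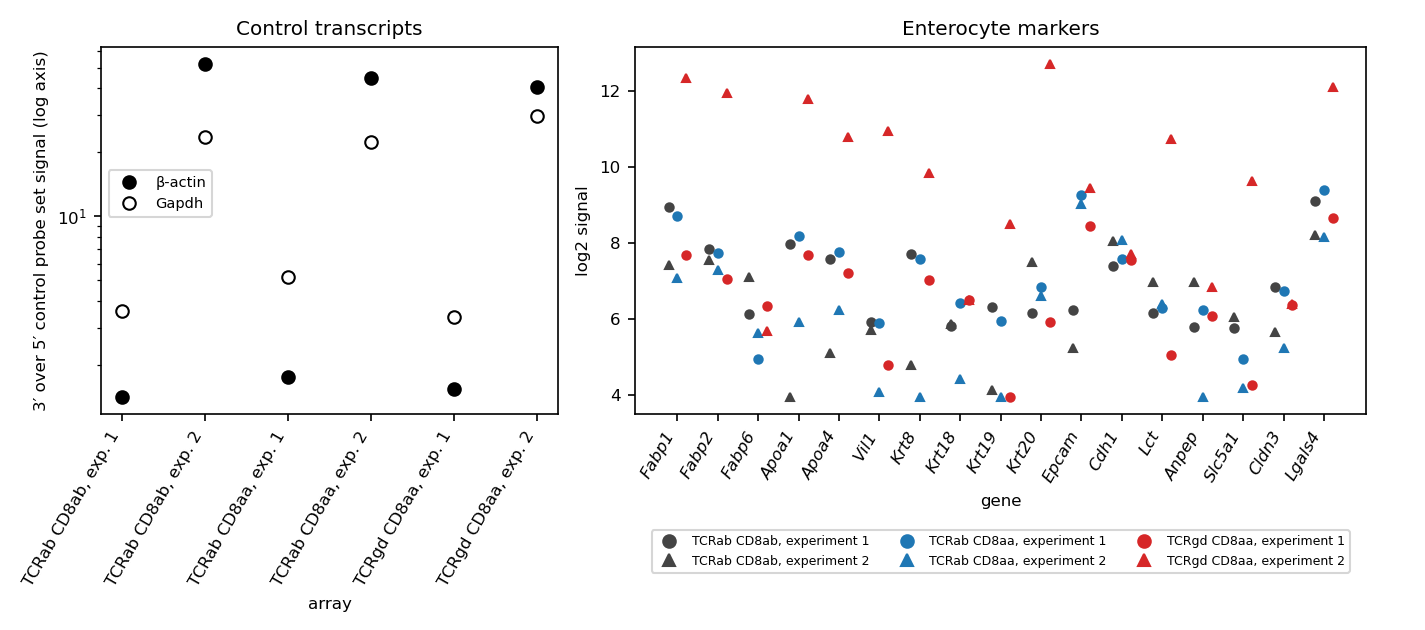
Left, the ratio of the 3′ to the 5′ control probe set signal for 2 transcripts on each array, on a log axis, where beta-actin lies between 1.41 and 1.76 in experiment 1 and between 40.4 and 52.2 in experiment 2. Right, log2 signal of each measured enterocyte marker on each array (points, coloured by subset, shaped by experiment), with Fabp1 at 12.33 in TCRgd CD8aa of experiment 2.

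The comparison of TCRab CD8aa with TCRab CD8ab asked how unconventional and conventional CD8 IEL with the same receptor type differ. Among the genes called with the block, TCRab CD8aa IEL had far less RNA for several surface molecules of conventional T cells. They had more for several receptors and adaptors typical of natural killer (NK) cells. The planned limma fit, without the block, called 0 probe sets (smallest adjusted p = 0.269). Cd5, a restrainer of T cell receptor signals, was lower by log2 −7.43 ± 0.47 (SE, n = 2), or at least 172-fold, since 1 of its TCRab CD8aa arrays lay at the floor. Fcer1g and Tyrobp, adaptors that carry signals of activating receptors, were higher by 5.03 ± 0.60 and 4.92 ± 0.53, the first also with 1 array at the floor. Zbtb16, the transcription factor PLZF of innate-like T cells, was at least 27.9-fold higher, since both TCRab CD8ab arrays lay at the floor. These 4 genes differed the same way in both experiments, which the rule that named them requires.

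The other genes with the largest increases in TCRab CD8aa were Itih5 (4.62 ± 0.32), Klra5 (4.54 ± 0.44), Klrb1a (4.32 ± 0.41), Klra7 (3.80 ± 0.59), Pkp2 (3.69 ± 0.34) and Klra6 (3.61 ± 0.44), with SE and n = 2. The Klra genes encode the Ly49 receptors of NK cells and Klrb1a a C-type lectin of the NK1.1 family. Other called probe sets carry several Klra symbols. Those named for 1 Klra gene may therefore also match others of the family and need not be separate signals. Tnfrsf21, a death receptor, was at least 11.9-fold higher. The largest decreases after Cd5 were Cd6 (−6.96 ± 0.60), Cd28 (−5.21 ± 0.67), Thy1 (−4.92 ± 0.36), Il7r (−4.72 ± 0.80), Klf2 (−4.42 ± 0.70), Pdcd1 (−3.92 ± 0.65), Gramd3 (−3.88 ± 0.72), Klf3 (−3.74 ± 0.62) and Cd2 (−3.58 ± 0.61). Cd28 is the main costimulatory receptor, Il7r the receptor of a survival cytokine, Klf2 a factor of circulating T cells and Pdcd1 the inhibitory receptor PD-1. For Klf2, Pdcd1 and Klf3, 1 array of the dimmer subset lay at the floor, and their differences are lower bounds. Rgs10, a regulator of G protein signals, was named by the fit without a block, with −3.20 ± 0.38. A probe set that carries several symbols of the Klra family was higher by 6.02 ± 0.51, a lower bound, as 1 TCRab CD8ab array lay at the floor.

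With the experiment as a block, limma called 68 of 8299 probe sets, 43 higher and 25 lower in TCRab CD8aa, for 56 genes with 1 symbol. A block of 2 experiments favours probe sets that moved the same way in both, and over all probe sets 53% did, or 73% of those that differed by at least 1 in both. Without the block limma called 0, with a smallest adjusted p of 0.269 and 187 probe sets at unadjusted p under 0.05. By chance 415 would be due if the arrays were independent, but they are paired by experiment. This fit leaves the difference between experiments in its spread, with a median residual SD of 0.707 against 0.421 with the block. A count under 415 is therefore no sign that the subsets are alike. The blocked count was 0 without the filter on dim probe sets, 6 without the intensity trend and 169 on the 4 arrays of these subsets alone. It was 34 and 22 without TCRab CD8aa replicates 1 and 2, 173 without TCRab CD8ab replicate 1, and 182 and 167 without TCRgd CD8aa replicates 1 and 2.

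**Figure D2:**
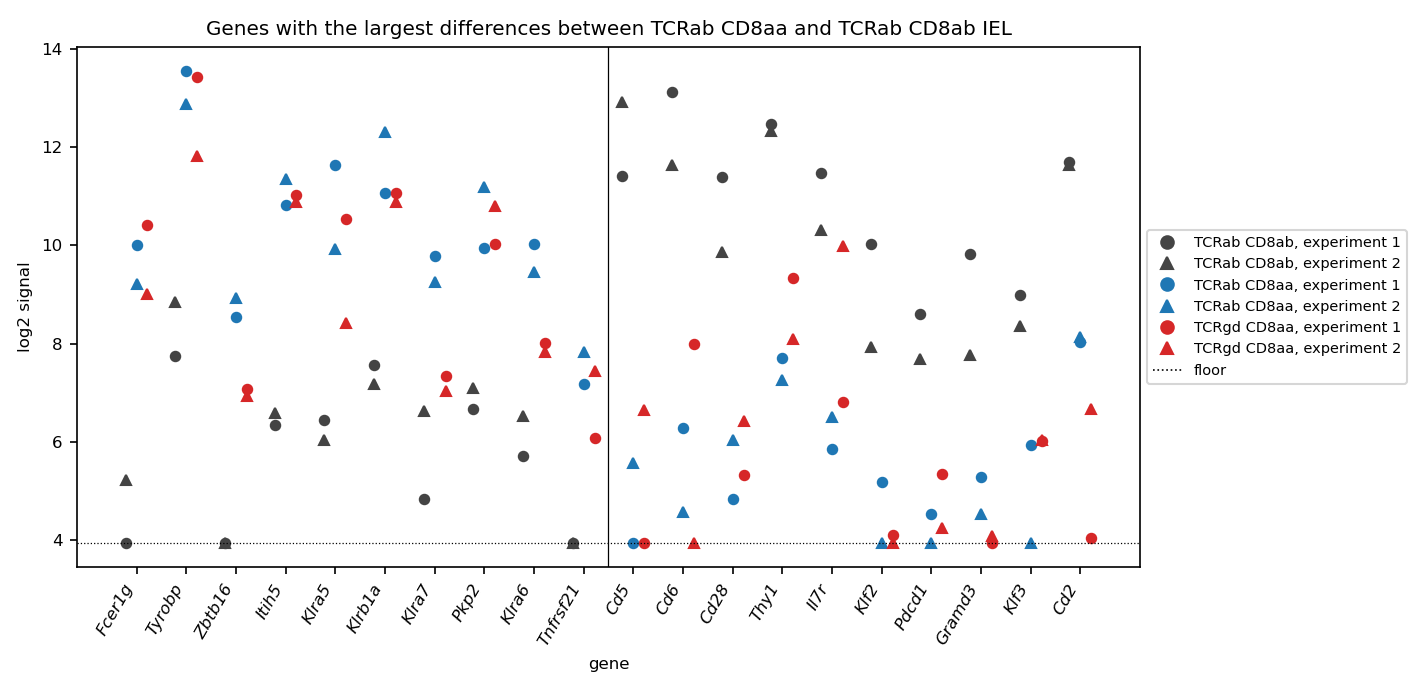
Log2 signal on each array (points, coloured by subset, shaped by experiment) of the 20 genes with the largest differences between TCRab CD8aa and TCRab CD8ab, the 10 higher in TCRab CD8aa at the left; the dotted line is the floor at 3.94. Both TCRab CD8ab arrays of Zbtb16 and Tnfrsf21 lie on the floor.

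The list of conventional naive and memory T cell genes fell in TCRab CD8aa as a group, with a median of log2 −2.49 over 18 measured genes, of which 16 were lower in both experiments (camera adjusted p = 1.53e-15; adjusted p = 0.158 with an estimated correlation). With the block 8 members were lower and 0 higher, and adjusted over the list alone 10 were lower and 1 higher with the block and 7 lower without it. Activating NK-type receptors and their adaptors passed as higher, with a median of 1.22 over 8 genes, 4 higher and 1 lower in both experiments (adjusted p = 4.28e-07; adjusted p = 0.177 with an estimated correlation), led by Klrb1a, Tyrobp and Fcer1g. The 3 were also higher adjusted over the list alone in both fits. Klrk1, the receptor NKG2D, had 0.26 in experiment 1 and 2.96 in experiment 2. Inhibitory NK-type and leukocyte receptors passed as higher through part of the list, with a median of 0.71 over 13 genes, 7 higher and 6 lower (adjusted p = 1.25e-05; adjusted p = 0.177 with an estimated correlation). Of these, 4 were higher with the block, among them Klra6 and Klra3 (2.86 ± 0.38), and 5 were higher without it adjusted over the list alone. All 4 were of the Klra family, whose probe sets need not be separate signals. Lilrb4a, also in this list, was not measured in it, as its called probe set carries several symbols. That probe set, looked up after the values were seen, was lower with the block by −2.165 ± 0.301 (limma adjusted p = 0.013).

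Cell cycle genes fell, with a median of −0.90 over 34 genes, 29 of them lower in both experiments (adjusted p = 1.28e-08; adjusted p = 0.177 with an estimated correlation). None passed over all probe sets in limma with the block, and adjusted over the list alone 10 were lower with the block and 0 without it. Cdc20, which drives exit from mitosis, had −1.35 ± 0.34 and Cdk1, the mitotic kinase, −1.55 ± 0.35. Cytosolic ribosomal proteins fell, with a median of −0.45 over 28 genes (adjusted p = 0.000152; adjusted p = 0.457 with an estimated correlation). Chemokines and their receptors fell, with a median of −0.57 over 16 genes (adjusted p = 0.0013; adjusted p = 0.177 with an estimated correlation), and adjusted over the list alone 2 were lower with the block. Cxcr3, a receptor for interferon-induced chemokines, had −1.70 ± 0.32, and Ccr9, the receptor that guides T cells to the small intestine, −1.40 ± 0.33. Interferon response genes fell, with a median of −0.42 over 26 genes, 14 lower in both experiments (adjusted p = 0.00174; adjusted p = 0.177 with an estimated correlation). Mx1 and Ifit3, antiviral effectors, had −2.66 ± 0.78 and −2.87 ± 0.73, the first with 1 array at the floor. No member of the lists of interferon response genes and cytosolic ribosomal proteins passed in either fit, even adjusted over the list alone. The list of cytosolic ribosomal proteins no longer passed without TCRab CD8aa replicate 2 (camera adjusted p = 0.264). The list of chemokines and chemokine receptors did not pass without TCRab CD8ab replicate 1 (0.242), and that of interferon response genes without that array (0.191) or TCRab CD8aa replicate 2 (0.0798).

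The other 11 lists did not pass camera without a block in this comparison. Members called with the block among them were Irf8 (2.72 ± 0.29), a factor of myeloid and lymphoid lineages, Txk (1.80 ± 0.31), a kinase of T cell receptor signalling, Fgl2 (1.81 ± 0.29) and Tgfb3 (1.99 ± 0.36) as increases. Gzmk (−2.99 ± 0.44), a granzyme, Tnfsf11 (−3.26 ± 0.60), the ligand RANKL, Irf4 (−3.35 ± 0.36) and Rora (−2.87 ± 0.46), transcription factors, were lower. Zbtb16, Cd5, Pdcd1, Cd28 and Cd2, given above, are also members of these lists. The medians were 0.17 for cytotoxic granule genes, 0.06 for cytokines, −0.11 for negative regulators of signalling, −0.11 for proximal T cell receptor signalling and −0.24 for immediate early genes. They were −0.11 for heat shock genes, −0.06 for gut homing genes, −0.13 for lineage transcription factors, −0.03 for apoptosis genes, −0.20 for oxidative phosphorylation and −0.36 for glycolysis. The mean of the cytokine list was −0.57 and its test pointed down, and the tests of the lineage factors and apoptosis genes pointed up while their medians and means were negative. Oxidative phosphorylation passed with the block (adjusted p = 0.0482; adjusted p = 0.576 with an estimated correlation).

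The comparison of TCRgd CD8aa with TCRab CD8ab asked how IEL with the other receptor type differ from conventional CD8 IEL. Among the genes called with the block, TCRgd CD8aa IEL also had less RNA for several conventional T cell surface molecules and more for several NK-type receptors and adaptors. The planned limma fit, without the block, called 0 probe sets (smallest adjusted p = 0.265). Cd5 was lower by log2 −6.88 ± 0.47 (SE, n = 2), or at least 118-fold, and Cd2, an adhesion receptor of T cells, by −6.31 ± 0.61. Fcer1g was higher by 5.13 ± 0.60 and Tyrobp by 4.33 ± 0.53. Zbtb16 was at least 8.38-fold higher, against TCRab CD8ab arrays at the floor.

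The other genes with the largest increases in TCRgd CD8aa were Itih5 (4.49 ± 0.32), Klrb1a (3.61 ± 0.41), Pkp2 (3.54 ± 0.34), Napsa (3.26 ± 0.45), Klra5 (3.25 ± 0.44), Adh1 (3.24 ± 0.34), Epcam (3.20 ± 0.50) and Myo6 (3.13 ± 0.38), with SE and n = 2. Epcam is an adhesion molecule of epithelial cells, and markers of enterocytes were raised on the TCRgd CD8aa array of experiment 2, with Fabp1 at log2 12.33 against 7.09 and 7.42 in the other subsets. The other decreases were Cd6 (−6.42 ± 0.60), Klf2 (−4.96 ± 0.70), Gramd3 (−4.78 ± 0.72), Cd28 (−4.76 ± 0.67), Sh2d1a (−3.90 ± 0.56), Thy1 (−3.69 ± 0.36), Rgs10 (−2.87 ± 0.38) and Irf4 (−2.77 ± 0.36). Sh2d1a encodes SAP, an adaptor of SLAM family receptors. For Cd5, Fcer1g, Cd6, Klf2, Gramd3 and Sh2d1a, 1 array of the dimmer subset lay at the floor, and their differences are lower bounds. A probe set unnamed here, as the annotation does not list it, was higher by 6.57 ± 0.32.

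With the block limma called 46 probe sets, 28 higher and 18 lower in TCRgd CD8aa, for 37 genes. Over all probe sets 51.5% had the same sign in both experiments, or 62.6% of those that differed by at least 1 in both. Without it limma called 0, with a smallest adjusted p of 0.265 and 168 probe sets at unadjusted p under 0.05. The 415 due by chance for independent arrays is again no fair measure, as that fit leaves the difference between experiments in its spread. The blocked count was 0 without the filter and 3 without the intensity trend. It was 97 and 30 without TCRab CD8ab replicates 1 and 2, 193 without TCRgd CD8aa replicate 1, and 66 without TCRgd CD8aa replicate 2, the array with raised enterocyte markers.

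Conventional naive and memory T cell genes fell in TCRgd CD8aa, with a median of log2 −2.24 over 18 genes, 15 of them lower in both experiments (camera adjusted p = 8.37e-17; adjusted p = 0.158 with an estimated correlation). With the block 7 members were lower, and adjusted over the list alone 11 were lower with the block and 6 without it. Activating NK-type receptors passed as higher, with a median of 0.63 over 8 genes, 3 higher and 1 lower in both experiments (adjusted p = 1.93e-06; adjusted p = 0.177 with an estimated correlation), again with 3 members higher in both fits adjusted over the list alone. Inhibitory NK-type receptors passed as higher, with a median of 0.30 over 13 genes, 9 higher and 4 lower (adjusted p = 7.81e-05; adjusted p = 0.178 with an estimated correlation). With the block 2 were higher, Klra3 (2.39 ± 0.38) and Klra5, whose probe sets again need not be separate signals. Adjusted over the list alone 5 were higher and 1 lower with the block and 4 higher without it. Klrd1, the partner chain CD94 of NKG2 receptors, had 1.74 ± 0.31.

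Cell cycle genes fell, with a median of −1.03 over 34 genes, 30 lower in both experiments (adjusted p = 5.45e-12; adjusted p = 0.158 with an estimated correlation), and 15 were lower with the block adjusted over the list alone and 0 without it. Cdk1 had −1.69 ± 0.35, Rrm1 −1.55 ± 0.45 and Rrm2 −2.0 ± 0.42, the last 2 being subunits of ribonucleotide reductase. Cytosolic ribosomal proteins fell, with a median of −0.46 over 28 genes (adjusted p = 0.000222; adjusted p = 0.458 with an estimated correlation), and Rps19 was lower with the block by −1.65 ± 0.29. Chemokines and receptors fell, with a median of −0.75 over 16 genes (adjusted p = 0.000222; adjusted p = 0.177 with an estimated correlation), and Xcr1 had −1.75 ± 0.60 and Cxcr3 −1.38 ± 0.32. Interferon response genes fell, with a median of −0.35 over 26 genes (adjusted p = 0.00608; adjusted p = 0.195 with an estimated correlation), and Ifit3 had −2.33 ± 0.73, with 1 array at the floor. No member of the interferon list passed in either fit, even adjusted over the list alone. Without TCRab CD8ab replicate 1 the lists of inhibitory NK-type and leukocyte receptors, chemokines and chemokine receptors, and interferon response genes did not pass (camera adjusted p = 0.0605, 0.136 and 0.267). Without TCRgd CD8aa replicate 1 the chemokine list did not (0.0832), and without TCRgd CD8aa replicate 2 the lists of interferon response genes and cytosolic ribosomal proteins did not (0.238 and 0.0826).

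The other 11 lists did not pass without a block. Fgl2 (2.17 ± 0.29) and Irf8 (2.47 ± 0.29) were higher with the block, and Ctla4 (−1.66 ± 0.28), an inhibitory receptor, was lower. Zbtb16, Cd5, Cd2, Cd28 and Irf4, given above, are also members of these lists. The medians were 0.43 for cytotoxic granule genes, −0.19 for cytokines, 0.03 for negative regulators, −0.21 for proximal T cell receptor signalling, 0.04 for immediate early genes and 0.24 for heat shock genes. They were 0.17 for gut homing genes, −0.28 for lineage transcription factors, 0.17 for apoptosis genes, −0.19 for oxidative phosphorylation and −0.20 for glycolysis. The cytokine test pointed up against a negative median and mean. The mean of the negative regulators was −0.39 and that of the immediate early genes −0.02, against positive medians. Cytotoxic granule genes passed with the block (adjusted p = 0.0314; adjusted p = 0.49 with an estimated correlation), with 13 of 15 members higher.

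**Figure D3:**
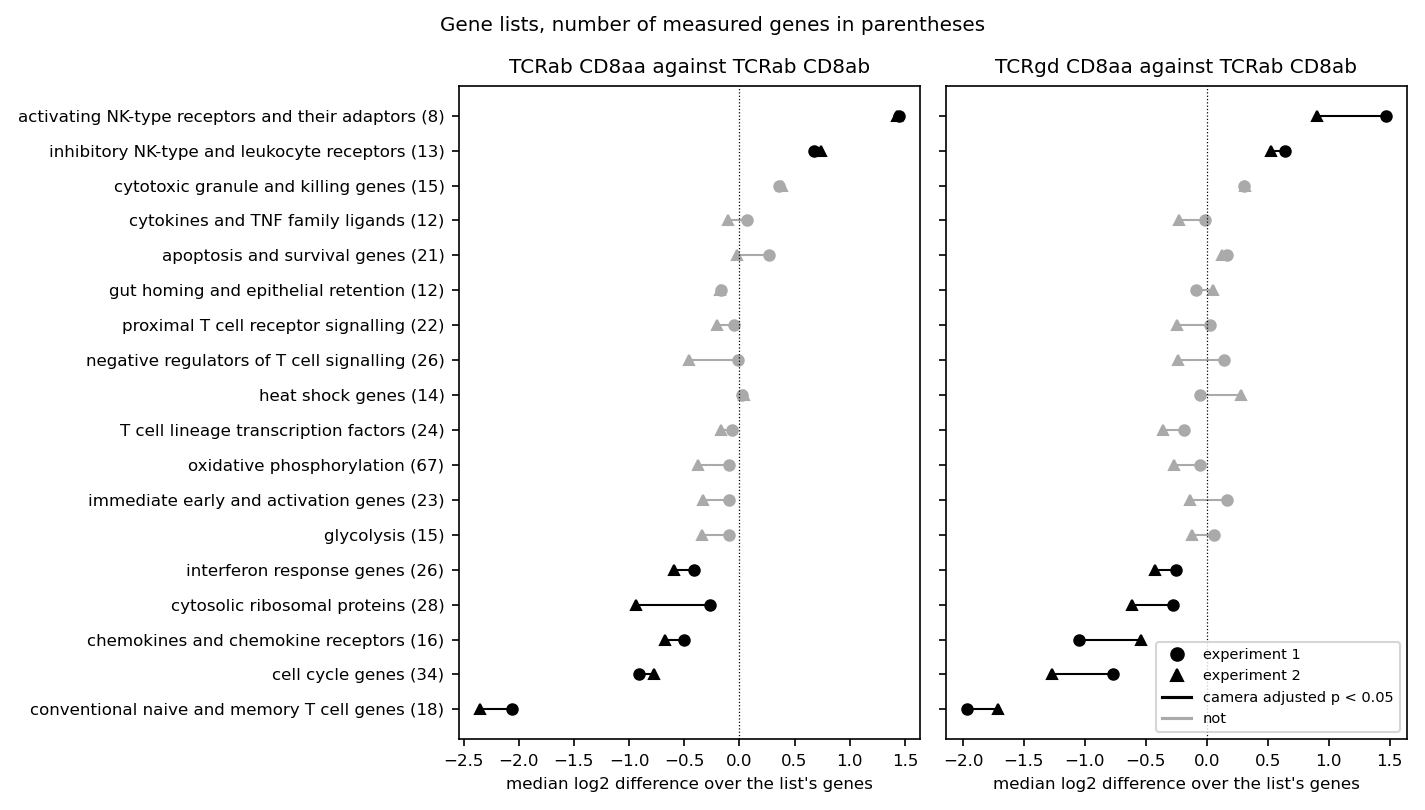
Median log2 difference of each gene list in experiment 1 (circles) and experiment 2 (triangles), for both CD8aa subsets against TCRab CD8ab, with the number of measured genes beside each name. Black marks lists with a camera adjusted p under 0.05 at the preset correlation, among which conventional T cell genes have medians of −2.06 and −2.35 in TCRab CD8aa.

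Both CD8aa subsets differed from TCRab CD8ab in many of the same probe sets. With the block 40 probe sets were called in both comparisons in the same direction, 27 higher and 13 lower, and 0 in opposite directions. Independent lists of these sizes would share 0.15 higher and 0.054 lower. In 100 simulated draws with no subset changed and with shared reference arrays, the mean shared count was 0.35 and the highest 4. With no change to call, a low shared count was to be foreseen. These draws therefore cannot show how much of the 40 came from the shared TCRab CD8ab arrays. Without the block limma called 0 in either comparison, against 187 and 168 at unadjusted p under 0.05. The differences correlated across probe sets with r of 0.726, where shared arrays alone gave 0.499, and the covariance was 0.39 against 0.13. Pairs of differences with no array in common had r of 0.155 and 0.219. The shared count was 0 without the filter, 2 without the intensity trend, 25 and 18 without TCRab CD8aa replicates 1 and 2, and 79 without TCRab CD8ab replicate 1.

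The comparison of TCRgd CD8aa with TCRab CD8aa asked whether the receptor type separates cells of the same CD8 form. Few probe sets were called between these subsets, which does not show that few differ. Each subset had 2 arrays, and the differences of the 2 experiments correlated with r of 0.0024. The unnamed probe set described above was higher in TCRgd CD8aa by log2 5.95 ± 0.32 (SE, n = 2), and the probe set with several Klra symbols was lower by −4.46 ± 0.51. Both were chosen after their values were seen, as they carry no single symbol.

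With the block limma called these 2 probe sets, and without it 0, with a smallest adjusted p of 0.788 and 34 probe sets at unadjusted p under 0.05. The genes with the smallest p had log2 differences of 2.57 ± 0.54 for Cd151, 2.34 ± 0.65 for Penk, 2.01 ± 0.51 for Tomm20, 3.74 ± 0.92 for H2-Aa and 2.63 ± 0.80 for Sin3b. On the other side were Klra7 (−2.31 ± 0.47), Xcr1 (−2.12 ± 0.60), Klra6 (−1.81 ± 0.44), Cd2 (−2.73 ± 0.61) and Zbtb16 (−1.73 ± 0.52). The fit with the block also named Scin (2.14 ± 0.30), Plac8 (1.57 ± 0.32), Casp1 (1.54 ± 0.37), Mxd1 (2.56 ± 0.62) and Clic4 (−1.01 ± 0.29). For Penk, H2-Aa and Mxd1, 1 TCRab CD8aa array lay at the floor, and their differences are lower bounds. H2-Aa is also a marker of macrophages and dendritic cells, and the median of that list was 0.892 on TCRgd CD8aa replicate 2 against the other arrays of experiment 2, with H2-Ab1 at 8.13 there against 3.94 and 4.40. The blocked count was 0 without the filter, 1 with quantile normalization, the strict filter or no intensity trend, and 114, 5 and 1 without TCRgd CD8aa replicate 1, TCRgd CD8aa replicate 2 and TCRab CD8aa replicate 2.

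Heat shock genes passed as higher in TCRgd CD8aa than in TCRab CD8aa, with a median of 0.25 over 14 genes, 13 higher and 7 of them in both experiments, and medians of 0.07 and 0.44 in experiments 1 and 2 (camera adjusted p = 0.0281; adjusted p = 0.552 with an estimated correlation). Hsp90aa1, a cytosolic chaperone, had 0.89 ± 0.36, Hspa5, the chaperone of the endoplasmic reticulum, 0.36 ± 0.29, Hspa1a 0.64 ± 0.40 and Hspd1 0.51 ± 0.37. In experiments 1 and 2 Hspa1a had −0.19 and 1.47 and Hspd1 0.33 and 0.69. The list of heat shock genes did not pass without TCRgd CD8aa replicate 2, the array with raised enterocyte markers, with quantile normalization, or without TCRab CD8aa or TCRab CD8ab replicate 1 (camera adjusted p = 0.238, 0.073, 0.944 and 0.0605). It also did not pass without the filter or the intensity trend, and it passed with the block (adjusted p = 0.0016; adjusted p = 0.576 with an estimated correlation). Inhibitory NK-type receptors passed as lower (adjusted p = 0.0482; adjusted p = 0.431 with an estimated correlation), with a median of 0.00 and a mean of −0.29 that differ in sign, and passed in 8 of 19 alternatives. They did not pass camera with the block (adjusted p = 0.0676). The medians of the other 16 lists lay between −0.12 for both activating NK-type receptors and cell cycle genes and 0.27 for chemokines and their receptors, whose mean was −0.03. They were 0.14 for cytotoxic granule genes, 0.23 for cytokines, 0.06 for conventional T cell genes, 0.07 for negative regulators, −0.09 for proximal signalling, 0.14 for immediate early genes and 0.14 for gut homing genes. The remaining values were 0.02 for lineage factors (mean −0.21), 0.08 for interferon response genes, 0.04 for apoptosis genes, 0.09 for ribosomal proteins, 0.07 for oxidative phosphorylation and 0.15 for glycolysis.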

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

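All tests in this part were chosen only after the results they address were seen. The control probe sets for Dap, Lys, Phe and Thr, RNAs usually added before labelling, had median log2 signals of 9.88 to 10.42 on the arrays of experiment 1 and lay at the floor, 3.94, on those of experiment 2.

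The ratio of the 3′ to the 5′ control probe set of beta-actin was at least 40.4 on the arrays of experiment 2 and at most 1.76 on those of experiment 1, a rise of log2 4.67 to 5.21 in the 3 subsets. Scaling between arrays is argued against as the source of the differences between experiments, since 2923 probe sets differed after quantile normalization against 2827 before. Target RNA that covers mainly 3′ ends in experiment 2 may contribute, as the ratio rose in each subset. Labelling, mice and handling were not separated by the design, and no biological explanation was tested. Markers of the sex of the pooled mice, given below, also differed between the experiments.

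Markers of enterocytes were raised on the TCRgd CD8aa array of experiment 2, by a median of log2 4.48 over 16 markers other than Epcam, 13 of them by more than 1 over the mean of the other arrays of that experiment. Expression by the TCRgd CD8aa subset itself is argued against by the same median in experiment 1, −0.589. A change shared by all samples of experiment 2 is argued against by the other subsets, whose median difference between experiments was −0.984. RNA of epithelial cells in that sample may be the source, with Krt20 at log2 12.71, Fabp1 at 12.33 and Lgals4 at 12.09, although the sort for T cell receptor and CD8 would remove such cells. Igha at 15.68 and Jchain at 11.97, genes of plasma cells, and Clca1 of goblet cells at 11.39 were high on the same array. The plasma cell genes were not confined to it. Igha lay between 11.77 and 13.22 in experiment 1, and had 10.95 in TCRab CD8aa and 8.54 in TCRab CD8ab of experiment 2. Jchain had 9.4 in TCRab CD8ab of experiment 1.

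Epcam, an adhesion molecule of epithelial cells, was higher than in TCRab CD8ab in both CD8aa subsets and both experiments. In TCRab CD8aa, RNA of epithelial cells is argued against by 16 other enterocyte markers, whose median differences were 0.0514 and −0.513 in the 2 experiments, and in TCRgd CD8aa of experiment 1 by a median of −0.467 against 2.21 for Epcam. Scaling is argued against, as the smallest of the 4 differences of Epcam was 2.04 after quantile normalization. In TCRgd CD8aa of experiment 2 such RNA may account for the level, since the other markers rose by a median of 4.12 and Epcam by 4.19. Expression of Epcam by CD8aa IEL stays open as a hypothesis for the other 3 arrays, and no further test was run.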

How the results depend on the processing

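The counts with the experiment as a block under other settings or without an array were chosen only after the data were seen; the other alternatives were planned. The probe sets changed without a block stayed at 0 in all 3 comparisons under every alternative except the replicate block, which gave 68 for TCRab CD8aa against TCRab CD8ab, 46 for TCRgd CD8aa against TCRab CD8ab, 2 for TCRgd CD8aa against TCRab CD8aa and 40 changed alike in both CD8aa subsets. The block's own construction, which takes the difference between experiments out of the spread, accounts for this. In the same order the replicate block gave 0, 0, 0 and 0 with no filter and 6, 3, 1 and 2 with eBayes without the trend. For the first comparison it gave 169 with only the 4 arrays of the 2 groups and 109 with adjusted p under 0.10, and for the third 1 with quantile normalization and 1 with the strict filter. Without each array in turn, the blocked counts ranged from 22 to 182, from 30 to 193 and from 1 to 114, and those changed alike from 18 to 79, where the lone array of a subset was assumed to vary like the other groups. The cause of these shifts was not tested.

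The gene lists shifted were 7 in each comparison with TCRab CD8ab and 2 in TCRgd CD8aa against TCRab CD8aa. They were 0, 0 and 0 for camera with an estimated correlation and 0, 0 and 0 for fry. For TCRgd CD8aa against TCRab CD8ab they ranged from 4 to 8 without each array. For TCRgd CD8aa against TCRab CD8aa they were 1 with the floor at the 30th percentile, 0 with no filter, 4 with the strict filter, 0 with eBayes without the trend and 1 with the replicate block, and ranged from 0 to 3 without each array. The cause was not tested.

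Of 269 named pairs of gene and comparison, 46 turned direction under at least 1 alternative, in 65 of 4237 recomputed values, and 4172 kept it. The replicate block brought 61 past the threshold, and 67 pairs had no value under the strict filter. Leaving out 1 array was the setting in all turns but 1, Rps28 in TCRgd CD8aa against TCRab CD8aa with quantile normalization (log2 −0.164). The log2 difference without each array is given below as its lowest and highest value for the 46; with 1 array left in a subset, its value rests on that array. That array belongs to 1 experiment and is set against arrays of both, so these ranges include the difference between experiments, and a turn of direction among them need not be a turn within an experiment. The same holds for the gene lists without an array. Cd3g, for example, had log2 0.445 and 0.43 in experiments 1 and 2 in TCRab CD8aa against TCRab CD8ab. In TCRab CD8aa against TCRab CD8ab, the ranges were Hspe1 −0.801 to 0.029, Cd8a −0.471 to 0.827, Cd4 −0.653 to 0.399, Cd3d −0.958 to 1.524, Cd3e −0.382 to 0.579, Cd3g −0.177 to 1.053 and Trav9d-3 −0.571 to 0.236. Further ranges there were Trbv1 −1.092 to 0.257. The range of Trav9d-3 is that of its brightest probe set, not of the one called in TCRgd CD8aa against TCRab CD8ab. In TCRgd CD8aa against TCRab CD8ab, the ranges were Gzmc −0.168 to 2.655, Dnaja1 −0.298 to 1.871, Pfkp −0.351 to 1.706, Slc2a3 −1.342 to 0.224, Cd8a −0.539 to 0.758, Cd4 −0.043 to 0.761 and Cd3d −1.227 to 1.318. Further ranges there were Cd3e −0.193 to 0.956, Cd3g −0.394 to 1.257 and Cd247 −2.053 to 0.403. In TCRgd CD8aa against TCRab CD8aa, the ranges were Pirb −0.305 to 2.023, Tyrobp −1.388 to 0.202, Syk −0.006 to 0.807, Gzmb −0.021 to 1.195, Gzmc −2.394 to 0.428, Csf2 −0.091 to 2.627 and Tnf −0.059 to 2.41. Further ranges there were Cd247 −0.096 to 2.36, Fos −0.155 to 0.949, Gadd45b −0.497 to 1.725, Hspa1a −0.384 to 1.669, Hspd1 −0.461 to 1.472, Rrm2 −1.563 to 0.279 and Prim1 −1.022 to 0.134. Further ranges there were Itgax −0.244 to 1.193, Itgb1 −0.579 to 0.007, Fas −0.107 to 2.125, Rps28 −0.018 to 0.798, Ldhb −0.144 to 0.856, Pfkm −0.623 to 1.213 and Ldha −0.187 to 0.546. Further ranges there were Cd8a −0.64 to 0.504, Cd8b1 −1.383 to 3.38, Cd4 −0.04 to 1.012, Cd3d −1.51 to 1.035, Cd3e −0.291 to 0.858, Cd3g −0.832 to 0.819 and Trbv1 −0.994 to 0.356. Signal at the floor of 3.94, where 17.1% to 24.5% of the probe sets of an array lay, limits the differences of dim probe sets among these.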

Other observations

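No hypothesis was tested in this part, and the genes named here beyond the rule were chosen after their values were seen. Kit, the receptor of stem cell factor, had log2 signals of 11.36 and 10.49 in TCRab CD8aa, 11.46 and 10 in TCRgd CD8aa, and 10.37 and 8.63 in TCRab CD8ab in experiments 1 and 2, and did not pass the threshold in limma. Ighm, the constant region of IgM, was higher in TCRab CD8aa than in TCRab CD8ab with the experiment as a block, by 1.85 ± 0.30 (SE, n = 2), but its tested probe sets differed in sign. Car2, carbonic anhydrase 2, lay between 13.54 and 14.66 on all 6 arrays, and Gzma, a granzyme of killer cells, between 13.78 and 14.64.

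Lists of markers of other cell types had the following median log2 differences, in the order TCRab CD8aa against TCRab CD8ab, TCRgd CD8aa against TCRab CD8ab and TCRgd CD8aa against TCRab CD8aa. Enterocytes had −0.28, 1.71 and 1.6 over 17 genes, Paneth and goblet cells 0.17, 0.85 and 1.32 over 7, and B cells and plasma cells −0.43, 0.30 and 0.45 over 10. Macrophages, dendritic cells and granulocytes had −0.84, 0.24 and 0.64 over 12, mast cells 0.16, 0.25 and 0.08 over 6, and fibroblasts and endothelium −0.73, −0.13 and 0.50 over 6. Erythroid cells had −0.22, 0.33 and 0.55 over 3, NK cells −1.23, −1.04 and 0.18 over 2, and Cd4 alone −0.13, 0.36 and 0.49. With the block limma called 1 gene of these lists, Epcam, in both comparisons with TCRab CD8ab, and Ighm in the first, and without it 0. Of the 8 genes of the NK cell list 7 are also in another list, and of the 4 of the CD4 T cell list 2 are.

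Markers of the sex of the pooled mice differed between the experiments. Eif2s3y, a gene of the Y chromosome, lay between 3.94 and 3.97 in experiment 1 and between 10.36 and 11.71 in experiment 2. Xist, expressed from the inactive X chromosome, lay between 11.21 and 11.96 in experiment 1 and between 6.85 and 8.66 in experiment 2. Uty, of the Y chromosome, lay between 3.94 and 4.23 in experiment 1, and had 6.75 in TCRab CD8aa, 5.92 in TCRab CD8ab and 3.94 in TCRgd CD8aa in experiment 2. The median differences of this list between subsets were 0.41, −0.59 and −0.66 over 3 genes. They mix Xist with genes of the Y chromosome and so do not measure a difference in sex.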
